A study of Homo sapiens with 6 samples.

How the data were processed

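Total RNA of MDA-MB-231 cells was extracted with a Trizol-type kit and made into Illumina libraries, per the labels' protocols. The labels give 6 samples in 2 groups, 3 with the vector and 3 with ADAMTS1. They do not state that the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Whether RNA was selected by poly(A) tail or depleted of ribosomal RNA, and whether the libraries keep strand, was not given in the sources used here. Without a strand setting, reads of a gene and of an antisense partner cannot be told apart.

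The values used were the FPKM per gene and sample (fragments per kilobase of transcript, scaled to the library's mapped total) that the authors deposited in a table of the series. FastQC, HISAT2 and StringTie are named, with the genome build hg38, per the submitters' processing notes, which give no versions, roles or annotation. Reads were not realigned. FPKM divides by transcript length and by the library's total, so it corrects for depth and shows changes relative to the rest of the library. It is not a count, and no count test was used. The absolute depth is unknown. Relative depth was recovered from the steps between low FPKM values (0.02 to 0.5), which lie at ratios set by whole numbers of fragments: in each of the 15 pairs of libraries at least 697 of at least 5439 genes shared the commonest ratio. It was 1.000, 1.174 and 1.260 for the vector libraries and 1.409, 1.044 and 1.429 for the ADAMTS1 libraries, relative to the first. The FPKM sum per library was 259395, 259289 and 260846 in the vector group and 261570, 263001 and 259612 in the ADAMTS1 group, with 23513 to 25040 genes above 0.

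The table had 32119 entries. For 284 that repeated a symbol, the entry with the highest mean was kept, which left 31835 genes; 8578 entries had no symbol and kept their gene identifier. Gene positions are those of the deposited table (hg38). GENCODE 29, used here for gene types, GC content and transcript length, had an entry for 96.9% of genes, and 99.92% of these overlapped the table's position. Of the tested genes 10187 were protein-coding. Correlations of log2(FPKM + 1) over tested genes were 0.9906 to 0.9929 within groups and 0.9886 to 0.9921 between groups, and no pair of libraries held the same values. The first principal component (28.2% of the variance) had the 3 vector libraries at −11.84, −5.76 and −4.18 and the ADAMTS1 libraries at 5.22, 10.82 and 5.74. The labels give no batch or date.

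Genes with a mean FPKM of at least 1 over the 6 libraries (11897) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(FPKM + 1). The 2 groups were compared with no further term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided. The pseudocount of 1 reduces the fold change of low genes. The fit had 4 residual and 3.191 prior degrees of freedom, and the median standard error was 0.0581. Relative depth was computed with Python 3.11.15 and NumPy 2.4.6, and plots were drawn with Matplotlib 3.10.9.

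The groups, the test, the alternatives, the lists and the naming rule were fixed before the data were examined. The rule named ADAMTS1, then the 12 genes that rose and the 12 that fell most among protein-coding genes past the threshold with groups that did not overlap and a mean FPKM of at least 5 in the higher group. It also named, for each list, up to 4 members past the threshold over all genes, or the 2 with the highest mean FPKM where none passed. Only 6 genes met the first part, ADAMTS1 included, and SPARC was named by the list part.

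Lists were fixed from textbook knowledge of pathways, of ADAMTS1 and of breast cancer, with signs of RNA quality and markers of other cell types. They cover the ADAMTS family, ADAMTS1 substrates, ERBB genes, mesenchymal and epithelial genes, matrix proteases, metastasis genes, drug efflux, drug metabolism, NRF2 targets, DNA repair (2 lists), proliferation, replication, apoptosis (2 lists), stemness, TGF-beta, YAP, NF-kB and interferon targets, antigen presentation, hypoxia, glycolysis, respiratory chain, unfolded protein response, ATF4, cholesterol, angiogenesis, immediate early genes, heat shock, ribosomal proteins, mitochondrially encoded genes, histones, and luminal, fibroblast, haematopoietic, endothelial and embryonic kidney markers. Some genes and 1 list are not reported here. Of 1063 list memberships 1009 were matched in the table. Lists with at least 5 tested members (35 of 40) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Alternatives were camera with a correlation estimated for each list, and fry. Members were also adjusted over their list alone.

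Results were also computed with a pseudocount of 0.1, no filter on low values or a mean FPKM of at least 5, scaling to a common upper quartile, by the median of ratios or to a common sum of FPKM, eBayes without trend or robust, the replicate number as a block, and each library left out in turn, all chosen beforehand. Genes below a mean FPKM of 5, SPARC among them, and lists with fewer than 5 members above it were not tested at that filter. A correction that removed each library's smooth trend with GC content and transcript length (splines with 4 degrees of freedom, on the 99.5% of tested genes with both values) was added after the data had been seen. A direction was called only for results past the threshold. Count tests were not run, because the values are FPKM, and term enrichment was not run, because the table pairs no terms with genes.

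The scripts were tested on simulated data made from the real means. For the comparison of ADAMTS1 with vector (11914 simulated genes), 36% of 50 genes changed by 0.25 on the log2 scale were recovered, 84% of those changed by 0.5, 92% of those changed by 1 and 92% of those changed by 2, with 3 false calls among 155. The adjustment is looser where more genes change, and the real comparison gave 8 calls. These shares therefore overstate recovery in the real comparison. There ESM1, with a log2 change of 0.79, did not pass (limma adjusted p = 0.0753). In a simulation of lists (11907 genes), 5 of 5 lists of 20 genes moved by 0.1 were called by camera and 0 of 30 others. With an estimated correlation 4 of the 5 were called, and fry called the 5 and 1 of the 30 others. The simulated genes were drawn independently of each other. These counts therefore do not show how often camera at the preset correlation calls unmoved lists whose members are correlated.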

Results

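Gene expression was measured by RNA-seq in MDA-MB-231, an established line of triple-negative breast cancer cells with a mesenchymal appearance. There were 6 libraries, 3 from cells with the vector and 3 from cells that overexpressed ADAMTS1. ADAMTS1 encodes a secreted metalloprotease with thrombospondin motifs, made as an inactive zymogen, that cleaves matrix proteoglycans such as versican. The series title places the comparison in a study of the nuclear zymogen in drug resistance and spread of breast cancer, so the question was which genes differ when ADAMTS1 is overexpressed. The form of ADAMTS1 that the construct encoded was not given in the sources used here. The deposited values were FPKM, and the absolute number of reads behind them is unknown. Relative to the first vector library, the depth of the other 2 vector libraries was 1.174 and 1.260, and that of the ADAMTS1 libraries was 1.409, 1.044 and 1.429. FPKM levels below are the mean ± SD of 3 libraries per group, vector first, and changes are ADAMTS1 minus vector on the log2(FPKM + 1) scale with their standard error.

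ADAMTS1 itself (ENSG00000154734, hg38 chromosome 21, 26835755 to 26845409, minus strand) rose 72.1-fold, from 6.76 ± 0.216 to 488 ± 22.3 FPKM. Its level was 6.56, 6.72 and 6.99 FPKM in the vector libraries and 499, 462 and 501 FPKM in the ADAMTS1 libraries, so every library matched its label. The change was 5.98 ± 0.040 (limma adjusted p = 8.8e-10). By mean FPKM the gene moved from rank 5880 to rank 38 among the 31835 genes listed, and its share of the summed FPKM rose from 0.0026% to 0.187%. Reads of the construct's coding sequence and of the endogenous gene were not separated.

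Beside ADAMTS1, 6 genes rose and 1 fell at an adjusted p under 0.05. The largest rise in fold among these was that of MMP1, the interstitial collagenase, which rose from 9.41 ± 0.377 to 14.1 ± 0.658 FPKM. LCP1, which encodes the actin-bundling protein L-plastin, was 1.42 times higher, from 10.8 ± 0.173 to 15.2 ± 0.528 FPKM. IGFBP3, an insulin-like growth factor binding protein, rose from 13.4 ± 0.282 to 16.9 ± 0.325 FPKM. THBS1, the matrix glycoprotein thrombospondin that inhibits angiogenesis, rose from 68.9 ± 1.70 to 83.7 ± 1.36 FPKM. PLAU, the urokinase plasminogen activator, rose from 102 ± 2.15 to 120.0 ± 0.942 FPKM. SPARC, a secreted collagen-binding matrix protein, fell from 3.37 ± 0.168 to 1.46 ± 0.255 FPKM, a ratio of 0.434. The non-coding RNA LINC02582 rose from 19.5 ± 0.353 to 28.5 ± 2.43 FPKM; it lies outside the naming rule and was chosen after its values were seen.

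The log2 changes were 0.54 ± 0.046 for MMP1, 0.46 ± 0.036 for LCP1, 0.31 ± 0.032 for IGFBP3, 0.28 ± 0.027 for THBS1, 0.24 ± 0.024 for PLAU, 0.52 ± 0.057 for LINC02582 and −0.83 ± 0.088 for SPARC. The limma adjusted p was 0.0198 for LCP1, 0.0246 for MMP1, 0.0417 for each of IGFBP3, THBS1 and PLAU, 0.0431 for SPARC and 0.0496 for LINC02582. In all 7 genes the 3 values of each group lay on separate sides, which chance gives in 10% of genes and which held for 18.8% of tested genes. The genes are spread over 7 chromosomes of hg38. MMP1 (ENSG00000196611) is at chromosome 11, 102789401 to 102798160, and PLAU (ENSG00000122861) at chromosome 10, 73909177 to 73917496. LCP1 (ENSG00000136167) is at chromosome 13, 46125920 to 46211871, and THBS1 (ENSG00000137801) at chromosome 15, 39581079 to 39599466. IGFBP3 (ENSG00000146674) is at chromosome 7, 45912245 to 45921874, and SPARC (ENSG00000113140) at chromosome 5, 151661096 to 151686975. LINC02582 (ENSG00000261780) is at chromosome 18, 73324941 to 73349879. With each library left out in turn, ADAMTS1 kept its call in all 6 fits, while THBS1, IGFBP3 and PLAU lost theirs in all 6, with an adjusted p of 0.0897 to 0.212. MMP1, LCP1, SPARC and LINC02582 kept theirs only without ADAMTS1 replicate 3 (adjusted p 0.0342) and reached 0.139 to 0.210 at the most without another library; no sign turned.

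**Figure D1:**
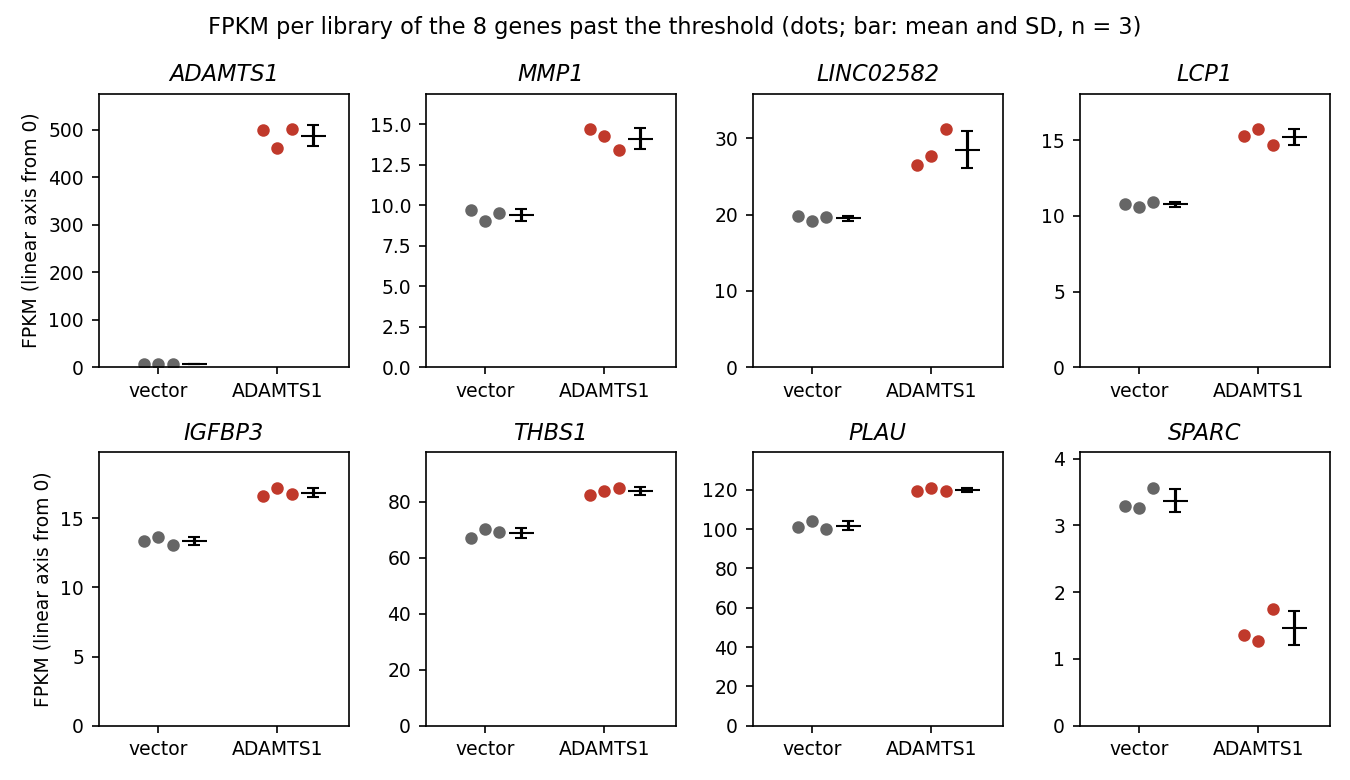
FPKM (vertical axes, linear from 0) of the 8 genes past the threshold in each of the 3 vector libraries (grey) and 3 ADAMTS1 libraries (red), with the mean and SD of each group as a bar. The groups do not overlap in any panel; ADAMTS1 goes from 6.76 to 487.5 FPKM and MMP1 from 9.41 to 14.1.

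Of 11897 genes tested by limma, these 8 (7 higher, 1 lower) passed the threshold, and ADAMTS1 was the only 1 that changed at least 2-fold on the log2(FPKM + 1) scale. The SPARC ratio of 0.434 is beyond 2-fold on the FPKM scale, while the added pseudocount reduces the log2 change of such a low gene. An unadjusted p under 0.05 was reached by 1452 genes (645 higher, 807 lower), where 595 would be given by chance. For 98.2% of tested genes the 95% interval of the change lay inside 2-fold in either direction, and for 213 genes it reached 2-fold. These intervals are on the log2(FPKM + 1) scale, where a low gene that differs 2-fold in FPKM can count as inside. GMFG, chosen after its values were seen, did so: its FPKM ratio was 0.484 and its interval −0.786 to −0.430. The count of 8 was 1 without vector replicate 1, 2 without vector replicate 2, 2 without vector replicate 3, 2 without ADAMTS1 replicate 1, 1 without ADAMTS1 replicate 2 and 5 without ADAMTS1 replicate 3. It was also 1 with no filter on low values and 31 among genes with a mean FPKM of at least 5.

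**Figure D2:**
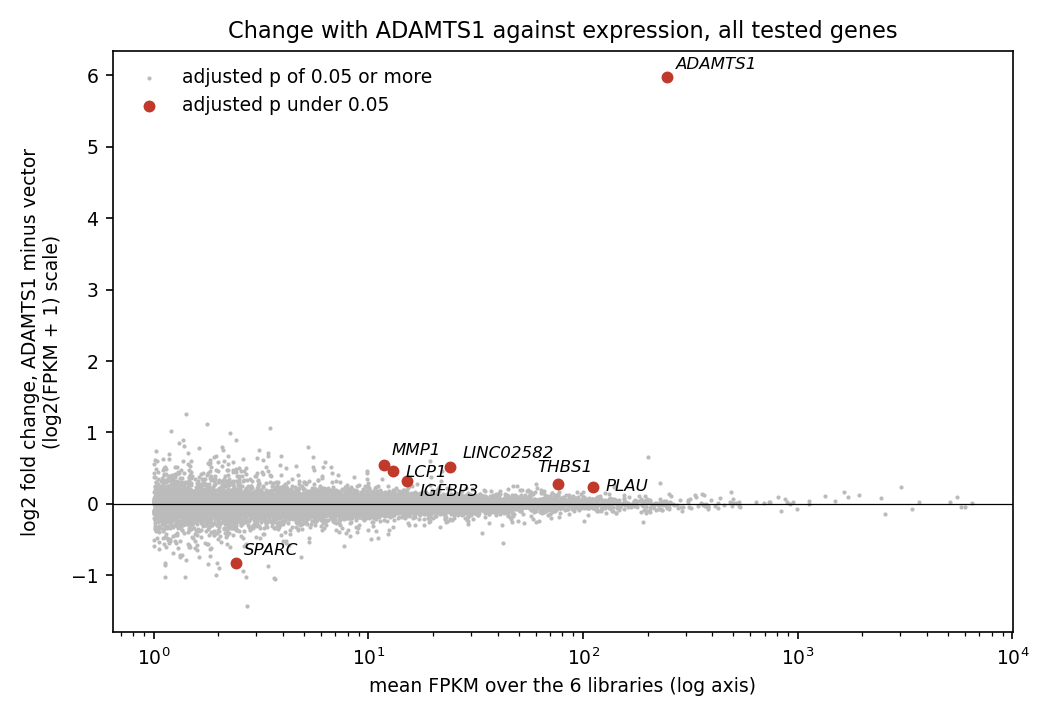
Change with ADAMTS1 (vertical axis, log2 scale of FPKM + 1) against mean FPKM over the 6 libraries (horizontal log axis) for the 11897 tested genes, with the 8 genes past the threshold in red. ADAMTS1 stands at 5.98, and the other 7 lie between −0.83 and 0.54.

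Gene groups were described with 40 lists fixed before the data were examined. By camera, 12 of the 35 lists with enough tested members passed the threshold, 7 higher and 5 lower. Their medians were small, from 0.020 to 0.29 in absolute log2 change. With a correlation between genes estimated for each list, 0 of the 12 kept the call (adjusted p 0.115 to 0.897), and each such p stands beside its list below. For histones, matrix proteases and replication the estimate (0.0096, −0.014 and −0.018) was not above the preset 0.01. Correlated members therefore do not account for the lost calls of these lists. The unadjusted camera p of histones still went from 3.9e-10 to 0.0033, so camera with an estimate is stricter even at a like correlation. A p with an estimated correlation is thus not a measure of correlation alone in any list. For the other called lists the estimate was higher, from 0.033 for antigen presentation to 0.306 for ribosomal proteins. fry, which asks whether the genes of a list move one way on balance, called 7 lists, and 6 of them were among the 12. Glycolysis, hypoxia, ATF4, NRF2 (fry adjusted p = 0.122), stem cell (0.0851) and ribosomal protein genes (0.665) did not pass fry. Their calls rest on camera at the preset correlation. Members are counted as changed when adjusted over the list alone; over all genes tested, the members past the threshold were MMP1, PLAU, THBS1, IGFBP3 and SPARC, and every list without any of these genes had 0. Members named below that are neither past the threshold over all genes nor, in a list with none past it, the 2 most abundant were chosen after their values were seen.

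Matrix proteases and their inhibitors were higher (21 tested, median 0.042, camera adjusted p = 1.2e-04; adjusted p = 0.135 with an estimated correlation). Adjusted over the list alone 7 rose and 1 fell, against 2 and 0 over all genes tested. Those past the threshold over all genes were MMP1 and PLAU. Over the list alone MMP3 (stromelysin) rose from 0.885 ± 0.187 to 1.48 ± 0.288 FPKM and ADAM19 rose from 5.91 ± 0.367 to 7.08 ± 0.164 FPKM. The plasminogen activator PLAT and the protease inhibitor SERPINE2 rose as well, and ADAM8 fell, by the same adjustment. The list median ranged from 0.012 with no filter on low values to 0.079 without ADAMTS1 replicate 1.

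Other extracellular and adhesion lists did not pass camera. Among described substrates and partners of the ADAMTS1 protein (9 tested, adjusted p = 0.132), adjusted over the list alone THBS1 rose and VEGFA fell, the latter from 14.3 ± 0.569 to 10.4 ± 0.816 FPKM. The same pair changed in the list of angiogenic factors (16 tested, adjusted p = 0.955), adjusted over that list alone; over all genes tested, THBS1 alone passed in either list. Of 8 other ADAMTS and ADAMTS-like genes tested, 0 changed (adjusted p = 0.955), and ADAMTS6 was at 8.88 ± 0.483 and 9.97 ± 0.382 FPKM. Of 17 mesenchymal genes (adjusted p = 0.710), adjusted over the list alone 2 rose, SNAI2 among them, and SPARC, LOXL2 and COL6A1 fell, against 0 and 1 over all genes tested. SNAI2, a transcription factor of the epithelial-mesenchymal transition, went from 5.02 ± 0.215 to 6.59 ± 0.144 FPKM, and LOXL2, a collagen cross-linking enzyme, went from 67.5 ± 2.76 to 56.9 ± 1.32 FPKM. Of 12 epithelial genes (adjusted p = 0.189), adjusted over the list alone the desmosome gene DSP rose by 0.28 ± 0.051 and the keratin gene KRT7 by 0.14 ± 0.033 on the log2 scale, while KRT18 was at 75.7 ± 2.10 and 72.7 ± 2.06 FPKM. Without vector replicate 1 this list passed (median 0.061, adjusted p = 0.0144). In the list of breast cancer metastasis genes (15 tested, adjusted p = 0.570), MMP1 rose and SPARC fell, over the list alone and over all genes tested.

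Replication-dependent histone genes, fixed beforehand as a sign of library chemistry, had the largest median of the 12 lists (0.29, 12 tested of 48, adjusted p = 1.4e-08; adjusted p = 0.115 with an estimated correlation). In all, 9 rose and 0 fell when adjusted over the list alone, against 0 over all genes tested. H2BC12 rose from 206 ± 6.55 to 252 ± 17.7 FPKM, H1-2 rose from 54.4 ± 2.78 to 66.5 ± 2.52 FPKM and H4C9 rose from 16.8 ± 0.877 to 22.3 ± 2.46 FPKM. These genes have near-identical copies, so how reads were divided among them is uncertain. With no filter on low values the median was 0.065. Replication genes were lower (39 tested, median −0.051, adjusted p = 0.0018; adjusted p = 0.135 with an estimated correlation). Of them 32 had a negative change, yet the only member past adjustment over the list alone was CCNE1, the cyclin that drives entry into S phase, which rose from 8.77 ± 0.0866 to 10.6 ± 0.366 FPKM. PCNA, the sliding clamp of DNA polymerase, was at 159 ± 4.33 and 152 ± 1.41 FPKM. Of 30 mitotic genes 0 changed (adjusted p = 0.714), and TPX2 was at 156 ± 1.11 and 158 ± 2.44 FPKM. Of 38 recombination and checkpoint genes 0 changed (adjusted p = 0.714; RPA1 54.6 ± 0.770 and 53.8 ± 0.757 FPKM). Of 30 end joining and excision repair genes 0 changed (adjusted p = 0.132; XRCC6 207 ± 3.79 and 201 ± 4.13 FPKM), and this list passed fry, downward (adjusted p = 0.0497), and camera without vector replicate 1 (median −0.033, adjusted p = 0.0406).

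Cholesterol synthesis and uptake genes were higher (24 tested, median 0.073, adjusted p = 2.5e-06; adjusted p = 0.135 with an estimated correlation). When adjusted over the list alone, 7 rose and 0 fell, against 0 over all genes tested. Among them were the sterol pathway enzymes MSMO1, from 17.5 ± 0.441 to 21.2 ± 0.820 FPKM, IDI1, from 14.5 ± 0.394 to 17.5 ± 1.53 FPKM, FDFT1, LSS and NSDHL, and the regulator INSIG1, from 19.4 ± 0.683 to 22.7 ± 1.10 FPKM.

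Glycolysis genes were lower (20 tested, median −0.075, adjusted p = 4.6e-05; adjusted p = 0.328 with an estimated correlation). Adjusted over the list alone 0 rose and 7 fell, against 0 over all genes tested. The lactate exporter gene SLC16A3 fell from 57.8 ± 3.12 to 47.9 ± 0.733 FPKM, the glucose transporter gene SLC2A1 fell from 37.1 ± 0.893 to 32.7 ± 1.10 FPKM and the hexokinase gene HK2 fell from 27.5 ± 0.894 to 24.6 ± 0.439 FPKM, and ENO2, PGK1, TPI1 and LDHA were the others. GAPDH was at 1018 ± 18.5 and 971 ± 21.6 FPKM and did not pass. Hypoxia-response genes were lower as well (22 tested, 2 of them shared with glycolysis, median −0.073, adjusted p = 0.0012; adjusted p = 0.328 with an estimated correlation). In all, 5 fell and 0 rose when adjusted over the list alone, against 0 over all genes tested: VEGFA, DDIT4, PFKFB4, BNIP3 and SLC2A1. DDIT4, a stress-induced inhibitor of mTORC1, fell from 38.7 ± 5.29 to 28.6 ± 1.76 FPKM, and the mitophagy receptor gene BNIP3 fell from 31.0 ± 1.97 to 26.3 ± 0.784 FPKM, while ADM was at 42.7 ± 1.11 and 44.2 ± 1.28 FPKM.

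ATF4 and amino acid response genes were lower (24 tested, median −0.063, adjusted p = 2.5e-04; adjusted p = 0.328 with an estimated correlation). When adjusted over the list alone, 4 fell and 0 rose, against 0 over all genes tested. ATF4 itself fell from 134 ± 1.55 to 122 ± 2.47 FPKM, SHMT2, the mitochondrial serine hydroxymethyltransferase, fell from 67.1 ± 2.80 to 61.2 ± 0.971 FPKM, and AARS1 and DDIT4 were the other 2. Of 27 ER chaperone and unfolded protein response genes 0 changed (adjusted p = 0.710), and HSPA5 was at 247 ± 1.88 and 265 ± 8.08 FPKM. Heat shock and cytosolic chaperone genes were higher (20 tested, median 0.038, adjusted p = 1.2e-04; adjusted p = 0.182 with an estimated correlation). Adjusted over the list alone 7 rose and 0 fell, against 0 over all genes tested, with HSP90AA1 rising from 783 ± 22.4 to 837 ± 12.1 FPKM and HSPH1 from 24.6 ± 0.334 to 27.1 ± 0.623 FPKM. This count lies close to the threshold. HSP90AA1, DNAJB4, CHORDC1, AHSA1 and DNAJA1 each had a limma adjusted p of 0.0499 over the list alone, and HSPH1 had 0.0454. The fry call of the list was close as well (adjusted p = 0.0497). HSP90AB1, the most abundant member, was at 1106.8 ± 25.8 and 1138.5 ± 12.4 FPKM and did not pass. NRF2 targets of the antioxidant response were higher (19 tested, median 0.034, adjusted p = 4.4e-04; adjusted p = 0.333 with an estimated correlation). In all, 5 rose and 0 fell when adjusted over the list alone, against 0 over all genes tested. The heme oxygenase gene HMOX1 rose from 8.18 ± 0.328 to 11.5 ± 1.46 FPKM, the ferritin light chain gene FTL rose from 2785 ± 88.6 to 3272 ± 160.4 FPKM, and TXN, TXNRD1 and GCLM rose by smaller amounts; FTL has many pseudogene copies that can share its reads. The NRF2 median was 0.014 without ADAMTS1 replicate 2 and 0.062 without ADAMTS1 replicate 1. Of 40 nuclear-encoded respiratory chain genes 0 changed (adjusted p = 0.571; CYC1 140.3 ± 2.92 and 141 ± 2.63 FPKM).

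Antigen presentation genes were lower (17 tested, median −0.085, adjusted p = 0.0013; adjusted p = 0.182 with an estimated correlation). When adjusted over the list alone, 2 fell and 0 rose, against 0 over all genes tested: HLA-B, with a change of −0.25 ± 0.034, and HLA-C, with −0.25 ± 0.037, which encode MHC class I heavy chains and resemble each other closely enough to share reads. The peptide-loading chaperone CALR was at 351 ± 4.46 and 354 ± 6.84 FPKM. The median was −0.0500 without vector replicate 1 and −0.0569 with no filter on low values. Interferon-stimulated genes did not pass (27 tested, adjusted p = 0.955), and adjusted over the list alone IFI44 rose from 43.0 ± 2.30 to 51.4 ± 2.70 FPKM and LGALS3BP fell from 53.8 ± 1.63 to 45.3 ± 1.63 FPKM, while ISG15 was at 130.1 ± 9.06 and 138 ± 11.7 FPKM. Nor did NF-kB targets and cytokines (23 tested, adjusted p = 0.714), where adjusted over the list alone IL24 rose from 4.37 ± 0.396 to 5.65 ± 0.316 FPKM and the cytokine genes CSF2, from 14.2 ± 1.27 to 10.7 ± 0.648 FPKM, and LIF, from 26.5 ± 0.565 to 23.8 ± 0.957 FPKM, fell.

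Among lists tied to drug response, 0 of the 8 drug efflux genes tested changed (adjusted p = 0.961), with ABCC1 at 13.9 ± 0.251 and 13.7 ± 0.825 FPKM. The list holds 15 genes. Those not tested, below a mean FPKM of 1 or absent from the deposited values, were not assessed. Of 22 drug and aldehyde detoxification genes tested, from a list of 30, 0 changed (adjusted p = 0.955), with GSTP1 at 108 ± 4.24 and 106 ± 3.39 FPKM. Of 14 anti-apoptotic genes 0 changed (adjusted p = 0.710; MCL1 126 ± 0.856 and 123 ± 1.77 FPKM). Of 19 pro-apoptotic genes 1 rose adjusted over the list alone (adjusted p of the list 0.955), the BH3-only gene PMAIP1, from 51.1 ± 1.86 to 57.9 ± 0.426 FPKM. In the list of breast cancer stem cell and pluripotency genes, the 9 tested of 19 listed were higher (median 0.082, camera adjusted p = 2.8e-04). Camera with an estimated correlation (adjusted p = 0.182) and fry (adjusted p = 0.0851) did not call the list. The other listed genes were not tested, so the rise does not cover the whole list. Adjusted over the list alone 2 rose and 0 fell, against 0 over all genes tested: the integrin gene ITGA6, from 61.9 ± 1.70 to 68.8 ± 1.19 FPKM, and the transcription factor gene SOX9, from 19.9 ± 0.701 to 21.9 ± 0.530 FPKM. CD44 was at 80.5 ± 2.77 and 83.6 ± 0.186 FPKM. The median of this list was 0.050 without vector replicate 3 and 0.054 without ADAMTS1 replicate 2.

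Signalling target lists did not pass camera. Of 22 TGF-beta targets (adjusted p = 0.147) 2 rose adjusted over the list alone, among them TGFBI, from 56.0 ± 2.78 to 63.1 ± 1.55 FPKM, while CCN2 was at 157 ± 2.13 and 155 ± 5.09 FPKM. Of 26 YAP and TAZ targets (adjusted p = 0.931) 2 rose adjusted over the list alone, IGFBP3 and the tissue factor gene F3, the latter from 59.1 ± 1.51 to 68.1 ± 1.33 FPKM; over all genes tested IGFBP3 alone did. Of 6 ERBB receptor and ligand genes 0 changed (adjusted p = 0.955; EGFR 29.5 ± 0.842 and 27.6 ± 1.18 FPKM), and of 22 immediate early genes 0 changed (adjusted p = 0.955; FOSL1 315 ± 10.1 and 305 ± 1.76 FPKM). The median, mean and test differed in sign for 8 lists that did not pass: the ADAMTS family, ERBB genes, drug efflux genes, both apoptosis lists, YAP and TAZ targets, NF-kB targets and immediate early genes.

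**Figure D3:**
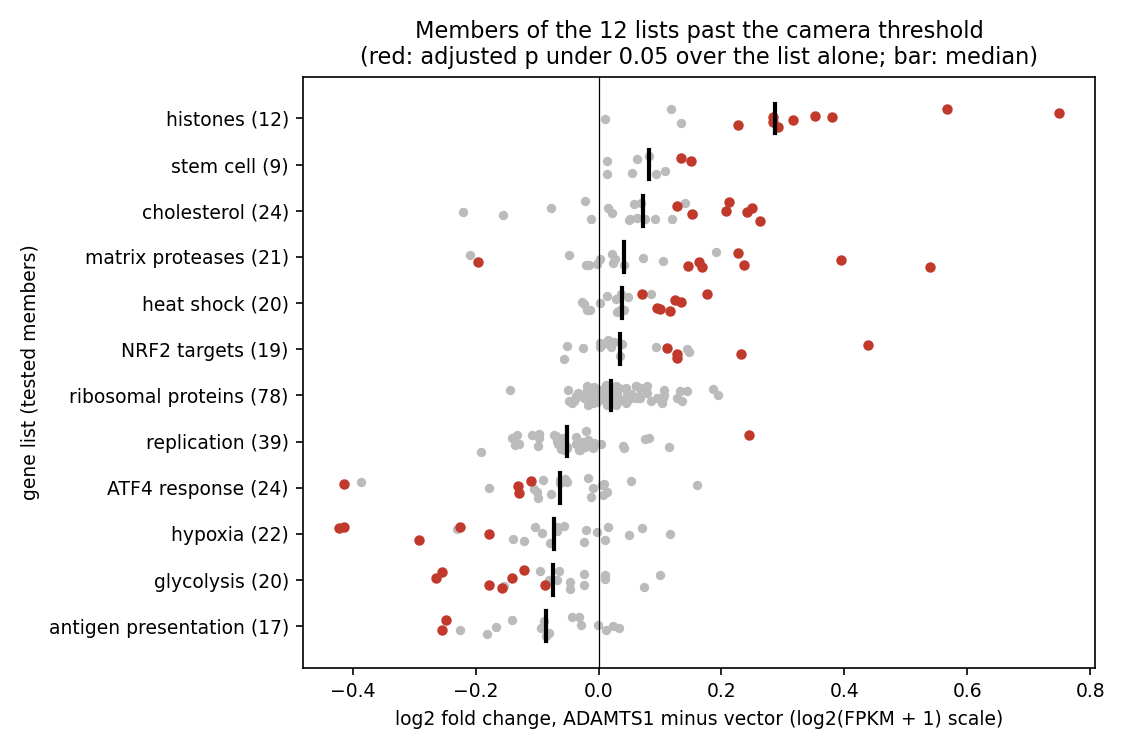
Change of each tested member (horizontal axis, log2 scale of FPKM + 1, ADAMTS1 minus vector) of the 12 lists past the camera threshold (vertical axis, number of tested members in brackets). Red marks members past an adjusted p of 0.05 over the list alone and the bar is the list median, from −0.085 for antigen presentation to 0.29 for histones.

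Ribosomal protein genes, most of which are abundant, were higher by a median of 0.020 (78 tested, adjusted p = 0.0037; adjusted p = 0.897 with an estimated correlation), and 0 members changed over the list alone or over all genes. RPS2 was at 884 ± 40.1 and 897 ± 27.1 FPKM. This call was lost without vector replicate 1 (adjusted p = 0.121), vector replicate 2 (0.104), ADAMTS1 replicate 1 (0.115) or ADAMTS1 replicate 2 (0.215), and after a correction for GC content and gene length (0.0555). The median was 0.0117 without vector replicate 1, 0.0122 without ADAMTS1 replicate 2 and 0.0115 when rescaled to a common sum of FPKM, and 0.0373 without vector replicate 3 and 0.0428 without ADAMTS1 replicate 3. Of 13 mitochondrially encoded genes, a sign of RNA quality, 1 fell adjusted over the list alone, MT-CYB, from 2685 ± 31.6 to 2426 ± 55.6 FPKM, and the list did not pass (adjusted p = 0.955). MT-CO1 was at 6458 ± 135 and 6516 ± 256 FPKM.

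Marker lists of other cell types had fewer than 5 tested members each and were not tested as sets. Of 4 luminal markers tested 0 changed over the list alone, with KRT19 at 38.3 ± 4.50 and 36.1 ± 1.21 FPKM, and ESR1 was below 1 FPKM in both groups. The fibroblast marker tested, COL1A1, was at 1.31 ± 0.0285 and 1.17 ± 0.163 FPKM, and the haematopoietic marker tested, LAPTM5, at 15.6 ± 0.898 and 15.9 ± 0.803 FPKM; neither changed. Of 2 endothelial markers tested, ESAM was at 45.8 ± 0.171 and 46.7 ± 2.84 FPKM, and TIE1 rose adjusted over the list alone, from 2.62 ± 0.228 to 3.82 ± 0.205 FPKM, while VWF, PECAM1 and CDH5 were below 1 FPKM in both groups. Of the markers of embryonic kidney packaging cells, 1 was tested, GAL, from 2.52 ± 0.411 to 3.18 ± 0.145 FPKM, with an unadjusted p of 0.0276 and so past the threshold over a list of 1. None of these markers passed over all genes tested.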

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

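The correction for GC content and gene length was chosen after the data had been seen; all others were chosen beforehand. The count of 8 genes became 1 with no filter on low values (more genes tested), 31 at a mean FPKM of at least 5 (fewer genes tested; 7 of the 8 are among them, and SPARC, whose mean is lower, was not tested), 3 when rescaled to a common sum of FPKM, 2 with eBayes without trend, and 1 to 5 when a library was left out (fewer samples). It was 6 to 9 under the other alternatives without a block, and where no cause is given the cause was not tested. With the replicate number as a block the count was 1, and that fit has fewer residual degrees of freedom. Deviations of same-numbered libraries from the group means correlated at −0.002, 0.018 and −0.093 over genes, and not every library correlated best with its own number. These values gave no sign of pairing. They cannot show whether same-numbered libraries shared a culture day or a preparation, since the labels give no batch or date. ADAMTS1 kept its call and a change of 5.96 to 6.15 in all 16 alternative fits, and the count of genes changed at least 2-fold stayed at 1. For the other called genes 67 calls were lost, and 10 named genes were called only at a mean FPKM of at least 5; none of the called genes changed sign. By camera, 11 to 14 lists passed in the 16 fits, and 11 of the 12 kept their call in all of them; ribosomal proteins lost it in 5. With an estimated correlation 0 lists passed and with fry 7. Of the other lists, breast metastasis genes passed at a mean FPKM of at least 5 (adjusted p = 0.0212), TGF-beta targets after the GC correction (0.035), and the epithelial and end joining lists with no filter (0.0251 and 0.0387) and without vector replicate 1. List members past the threshold, 83 memberships of 74 genes, were 55 to 65 when a library was left out and 57 to 87 otherwise. The scalings moved the median of all genes by less than 0.1. Absolute depth is unknown, so counting error at low FPKM is not known either.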

Other observations

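The test of S phase below was chosen after its result had been seen, and the correction for GC content and gene length is an alternative added after the data had been seen; the other tests were fixed before their results. Among genes with a mean FPKM of at least 5, where 31 passed (17 higher, 14 lower), several belong to no fixed list. All are named after their values were seen, none passed among all tested genes in the main fit (adjusted p 0.0595 to 0.108 there), and the adjusted p below are those of the stricter filter. Outside that filter, ESM1 also passed without vector replicate 2, and APOBEC3B and TGM2 after the correction for GC content and gene length. ESM1, which encodes the secreted proteoglycan endocan, rose from 3.56 ± 0.615 to 6.88 ± 0.476 FPKM (adjusted p = 0.0172). ZNF114, a zinc finger gene, rose from 6.10 ± 0.103 to 8.37 ± 0.669 FPKM. TGM2, a transglutaminase that cross-links proteins, rose from 53.8 ± 0.925 to 60.7 ± 0.347 FPKM, and YES1, a SRC-family kinase gene, rose from 47.5 ± 1.55 to 54.5 ± 0.796 FPKM. SAA1, an acute-phase apolipoprotein gene with a near-identical neighbour, fell from 9.44 ± 0.394 to 5.94 ± 0.633 FPKM (adjusted p = 0.0172). LAMA5, a laminin chain of basement membranes, fell from 46.2 ± 1.55 to 37.3 ± 2.12 FPKM, the keratin gene KRT80 fell from 33.1 ± 0.689 to 28.5 ± 0.356 FPKM and PHLDA2 fell from 109 ± 5.12 to 91.9 ± 1.43 FPKM. APOBEC3B, a cytidine deaminase gene with close paralogs, fell from 16.7 ± 0.223 to 13.8 ± 0.249 FPKM (adjusted p = 0.0241). By chromosome, 0 of 23 sets of tested genes passed camera (smallest adjusted p = 0.0504, chromosome 22, median −0.033).

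Histone genes were higher with ADAMTS1, with a median of 0.29, by camera at the preset correlation and by fry (adjusted p = 0.0217) but not with an estimated correlation (adjusted p = 0.115). A trend with GC content or gene length is argued against as the whole cause, since the median was 0.295 after that trend was removed and camera at the preset correlation still called the list. More cells in S phase were predicted to raise replication genes too. Their median was −0.051, past the threshold downward by camera at the preset correlation and by fry (adjusted p = 0.0149). The list did not pass camera with an estimated correlation (adjusted p = 0.135), and CCNE1, its only member past adjustment over the list alone, rose. Because the list mixes licensing with S phase genes and the test was chosen after its result, it does not settle the share of cells in S phase. Unequal capture of RNA without a poly(A) tail may be a source and cannot be told apart from an effect of ADAMTS1: 5 genes for such RNA had a median of 0.037 with a standard error of 0.185, too wide to exclude the 0.144 it would need. Reads shared among near-identical histone genes also stay open.

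MMP1, PLAU, THBS1, IGFBP3, LCP1 and LINC02582 were higher and SPARC lower. A broad difference in chromosome copy number between the cultures is argued against, because genes within 5 Mb of each had medians in its direction of at most 0.04, at MMP1, where 14 neighbours were tested. A copy number change of a stretch much shorter than this window could leave the median unmoved and was not tested. A trend with GC content or gene length is argued against as the whole cause, because each gene found higher or lower kept at least 0.949 of its change. LINC02582 lost its call as its change went from 0.52 ± 0.057 to 0.49 ± 0.062 (limma adjusted p = 0.0644). An effect of ADAMTS1 and a difference between the cultures that does not come from it both stay open, since the labels give no independent cultures.

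Glycolysis, hypoxia and ATF4 genes were lower and cholesterol genes higher by camera at the preset correlation. With an estimated correlation none of the 4 passed (adjusted p = 0.328 for the 3 lower lists and 0.135 for cholesterol). By fry cholesterol passed (adjusted p = 0.0188), and glycolysis (0.0617), hypoxia (0.0773) and ATF4 (0.0773) did not, so the 3 falls rest on that camera setting. A trend with GC content or gene length is argued against as the whole cause, because each list kept at least 0.716 of its median, with camera at the preset correlation calling all 4 in the same direction. The lists are not independent of each other: glycolysis and hypoxia share 2 members, and hypoxia and ATF4 share 1. Differences in density, medium or oxygen between cultures may move such genes and were not tested, and an effect of ADAMTS1 stays open beside them.

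The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. As many genes as the real 8 were given by 1 of the 10 splits, the real one, and the highest other count was 1. For genes changed at least 2-fold, 2 of the 10 splits gave as many as the real 1, and the highest other count was 1. For lists past the camera threshold, 1 of the 10 splits gave as many as the real 12, and the highest other count was 6.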
